A study of Mus musculus with 10 samples.

How the data were processed

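Gene expression was measured on 10 two-colour Agilent oligonucleotide arrays in 5 groups of 2 arrays. The groups were total RNA of mouse embryos at day 12.5 after conception, total RNA of placentas of the same age, and 3 pools of RNAs named TR076 and TR077 in ratios of 75 to 25, 50 to 50 and 25 to 75. Per the labels, 5 embryos or 5 placentas were combined in each unmixed RNA. The labels do not say which of TR076 and TR077 is embryo RNA, so the pools are named by their TR076 percentage and both readings are given where a value depends on it. Per the design text, each RNA was the template of duplicate linear amplification and labelling reactions, so the 2 arrays of a group are technical duplicates and p-values measure the spread of labelling and hybridisation, not of animals. Array numbers within a group name arrays and pair none. On each array the sample was labelled with Cy3, and a universal mouse reference RNA made from several cell lines was labelled with Cy5. Dyes were not swapped.

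Per the file headers, the authors extracted the scans with Agilent Feature Extraction A.7.1.1. The deposited scanner tables hold raw spot intensities with local background, processed intensities that are background-subtracted and dye-normalized, and a log10 ratio of Cy5 over Cy3. The deposited series matrix holds values on a log10 scale. Of its values, 89.7% lay within 0.001 of minus the log10 ratio plus the mean log10 Cy5 processed intensity of the probe, which settles the direction as sample over reference. How the remaining values were changed is not given in the sources used here. The column medians of the matrix lay between 2.996 and 3.011, with 3.007 and 3.004 for the embryo arrays, 2.996 and 2.999 for the placenta arrays, 3.009 and 3.009 for the 75% TR076 pool, 3.011 and 3.009 for the 50% pool and 3.007 and 3.003 for the 25% TR076 pool.

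Each array had 22132 spots, of which 1080 were controls (162 of them negative controls) and 21052 were gene probes. Mean signals were corrected against median local background by normexp with an offset of 50, and log ratios were normalized within each array by loess with weight 0 for controls and outlier-flagged spots. Values are log2 of Cy3 over Cy5. Outlier-flagged spots were set to missing, and saturated spots were kept. A probe was tested if its Cy3 signal was well above background on both arrays of at least 1 group, which left 20556 probes and removed 496. Linear models with moderated variances (limma 3.58.1 in R 4.3.3) were fitted to all 10 arrays, with 5 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. A probe below background or saturated on both arrays of a group has only a bound there. For it, a fold of at least N was taken from the Cy3 channel after loess and Aquantile normalization, with the dim group at the higher of its own signal and the lowest signal well above background, a value open to dye bias because no dyes were swapped.

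The files identify probes by sequence accession. Symbols were taken from the RefSeq table of assembly GRCm38.p6, which matched 10422 probes by transcript accession and 44 by synonym, matched none to several genes and left 10586 without a symbol. The files name no genome build, so no coordinates are printed. Where several probes named a gene, the probe with the highest mean intensity was used, and 9 of the 79 genes with 2 or more called probes had called probes in opposite directions.

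The expected ratio of 2 pools was computed by adding the linear ratios of embryo and placenta in the stated proportions. Observed log2 ratios of the 4 pairings of 2 arrays of each pool were regressed on it over the probes called between placenta and embryo. The embryo share of a pool is the median, over called probes with a log2 difference over 1, of the position of the pool's linear ratio between placenta and embryo. Shifts of 20 gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, whose directional p tests whether a list's genes move, on balance, one way. Genes with a missing value on any array in the fit, such as Prl8a9, Prl8a6, Hexb, Bub1, Amn and Kng1, were left out of these tests. The counts and medians given for a list include them. The gene lists, the tests of the report, the rule for naming genes and the alternatives, except 3 added later, were fixed before the data were examined. By that rule the text names the 10 genes with the largest called difference in each direction, 1 probe per gene, well above background on both arrays of the higher group and with a symbol that is not a clone name, up to 2 called members per direction of each list, and every measured placental prolactin gene. The same genes were followed through the pools. Other genes are named where a count is small, and were then chosen after their values were seen.

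The procedure, from the normalized log ratios onward, was tested on simulated data. With 200 changed probes among 20556 in a simulated placenta and embryo comparison, it called 97.0% of those changed by 0.5 on the log2 scale and 100% of those changed by 1 or by 2, and 4.81% of the calls were unchanged probes. Pools simulated from the measured embryo and placenta values, at embryo shares of 75%, 50% and 25%, returned shares of 74.9%, 50.0% and 25.5% and slopes of 0.985, 0.992 and 0.979 for the 75% against 25%, 75% against 50% and 50% against 25% pools. Noise was added independently per probe to normalized log ratios, so background correction, loess and the probe filter were not tested. Apart from 200 probes shifted in the 50% pool, the simulated pools followed a linear mix. Recovery of their shares therefore does not show that the real pools follow one. Tables were read with the data.table package. Alternatives to the background correction, normalization, probe filter, fit, and choice of arrays were run on the counts of 4 comparisons, the slopes, the embryo shares, the gene lists and the named genes, each where it applies. They were not run on the pool order, the overlap of calls, the counts between neighbouring pools, the Cy5 calls or the deviation from a linear mix. Each array had its own slide and no scan date was used, so slide and scan date were not tested as a batch.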

Results

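RNA from mouse embryos and placentas at day 12.5, and from 3 pools of RNAs TR076 and TR077, was hybridised in duplicate on 10 arrays against a common reference RNA. The purpose stated in the design text is to compare the log ratios measured between mixtures with those expected from the unmixed RNAs. Cy3 signals were well above background at 94.0% to 98.1% of gene probes per array. Median Cy3 signals were 588 to 782, which is 1.54 to 2.05 times the local background, and the median of the negative controls was 430 to 446. Between 7 and 38 probes per array were saturated in Cy3 and 86 to 108 in Cy5. Duplicate arrays correlated across probes at r = 0.978 to 0.989, and at least 99.9% of probes lay within 2-fold between duplicates. Their median SD per probe was 0.040 to 0.062 on the log2 scale. Embryo and placenta arrays correlated at a mean r of 0.494 across probes. The highest r between arrays of different groups was 0.975, below the lowest r within a group. Probes are not independent replicates, and the number of arrays limits the precision of each value.

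The comparison of placenta with embryo asked which transcripts differ between the unmixed RNAs. Of 20538 probes tested with limma, 9315 differed (45.4%, adjusted p under 0.05), of which 4455 were higher and 4860 lower in placenta. Differences over 2-fold were found at 2187 of these probes, 1142 higher and 1045 lower. The called probes named 5541 of the 10069 genes with a symbol, and 3688 called probes had no symbol.

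The genes with the largest rise in placenta were taken by the ratio to the reference, whose own signal rose at some of them. In Cy3 alone, genes outside this set stood above some of its members. Examples are Gzmd (8.42), and Prl3b1 and Cts3 with saturated spots, above Ceacam12, Ceacam13 and Procr (7.79, 7.25 and 6.19). Prl8a2, a decidual prolactin, rose by 6.43 ± 0.12 on the log2 scale (SE, n = 2 arrays per group, limma adjusted p = 1.17e-10). The set also held the trophoblast protein gene Tpbpb (log2 difference 6.35 ± 0.27, saturated on 1 placenta array), Prl2c2, a proliferin (6.19 ± 0.15), Ceacam12 (5.91 ± 0.22), the endothelial protein C receptor Procr (5.83 ± 0.06), Ceacam13 (5.81 ± 0.15) and Prl7d1 (5.73 ± 0.21). Sizes depended on the processing, with 5.28 to 9.04 for Prl8a2, 5.58 to 10.7 for Tpbpb and 4.90 to 10.4 for Prl7d1 over the alternatives. Embryo Cy3 signals at these probes, after subtraction of background, were only 65.3, 73.6 and 67.0, against an added offset of 50. Another 3 genes of this set, Prl7a2, Prl8a9 and Ceacam11, were saturated on both placenta arrays, where their Cy3 signals were at least 864-fold, 642-fold and 678-fold higher than in embryo. The genes with the largest fall were Sox2, a transcription factor of neural progenitors (−4.67 ± 0.11, adjusted p = 2.54e-10), Igfbp5 (−4.34 ± 0.08), the neurofilament gene Nefm (−4.04 ± 0.08), Nr2f1 (−4.00 ± 0.08), the brain lipid-binding protein gene Fabp7 (−3.98 ± 0.16), Tfap2b (−3.97 ± 0.11), Zfp521 (−3.92 ± 0.11), the mesenchymal transcription factor gene Twist1 (−3.90 ± 0.10), skeletal muscle actin Acta1 (−3.90 ± 0.08) and Cd24a (−3.87 ± 0.07). Their order too depends on the reference, whose signal was lower on placenta arrays at Sox2, Nefm, Fabp7 and Tfap2b. In the Cy3 channel after loess and Aquantile normalization, the difference was −5.38 at Fabp7 and −4.85 at Sox2. Sizes of the falls depended on the processing as well. Over the alternatives they were −5.24 to −2.66 for Nefm, −4.36 to −2.47 for Zfp521 and −4.34 to −2.57 for Twist1. The range was narrower for Acta1, −4.15 to −3.19. Without background subtraction, Sox2 fell by less than Fabp7 (−3.83). The placenta Cy3 signal at Sox2, after subtraction of background, was only 77.4, against the added offset of 50.

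All 15 measured members of the placental prolactin family rose, with a median log2 difference of 4.92 (camera adjusted p = 1.33e-08, and adjusted p = 0.107 with an estimated correlation). Beside those above, the log2 differences were 5.51 for Prl6a1, 4.92 for Prl2a1, 4.84 for Prl8a8, 3.96 for Prl7a1, 3.95 for Prl3c1, 2.90 for Prl4a1 and 1.54 for Prl3d3. Prl6a1 was well above background on 1 embryo array only. Embryo Cy3 signals after subtraction of background were 56.4 at Prl6a1, 69.4 at Prl3c1 and 86.0 at Prl3d3. Over the alternatives these 3 genes had differences of 3.89 to 8.12, 1.98 to 4.97 and 0.61 to 2.48, against 3.19 to 4.23 for Prl7a1. Prl8a6 and Prl7c1 were not well above background on either embryo array, and their Cy3 signals were at least 44.1-fold and 5.52-fold higher in placenta. For Prl7c1 the ratio differed by 1.44 ± 0.38 on the log2 scale, with an SD of 1.06 between the placenta arrays and 0.69 to 2.19 with 1 array left out, and its call was lost in 4 of 16 alternatives of the processing. Prl3b1, placental lactogen II, was saturated on both placenta arrays and its Cy3 signal was at least 561-fold higher there, whereas its log2 ratio to the reference differed by only 2.33 ± 0.41. The Cy5 signal of the reference at this probe, after subtraction of background, was 129 on embryo and 26490 on placenta arrays. A smaller Cy5 rise was measured at other strongly placental probes, for example from 41.2 to 1203 at Prl7d1 and from 62.7 to 1357 at Tpbpb, while Cy5 was 1932 and 2283 at Procr. Ratios at Prl7d1 and Tpbpb were smaller than the differences in the Cy3 channel after loess and Aquantile normalization, 8.98 and 9.46 on the log2 scale.

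All 18 measured genes of the spongiotrophoblast and giant cell list rose too (median log2 difference 3.69, camera adjusted p = 4.31e-11, and adjusted p = 0.0868 with an estimated correlation), among them Tpbpb and Ceacam11, Ceacam12 and Ceacam13. Of the 15 measured genes of the labyrinth and syncytiotrophoblast list, 13 rose and 1 fell (median 1.76, camera adjusted p = 5.44e-07, and adjusted p = 0.065 with an estimated correlation). Rhox6 rose by 5.50 on the log2 scale. Esx1, a homeobox gene of the labyrinth, was not well above background on embryo arrays and was at least 17.8-fold higher in placenta. The member that fell was the glucose transporter Slc2a3 (−0.37, adjusted p = 0.00171). Signal shared between near-identical members of the prolactin, Ceacam and other families was not separated.

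The placental proteases list, which also holds the protease inhibitors Serpinb9e, Serpinb9g, Timp2 and Timp3, moved both ways. Of its genes, 10 of 17 were higher and 5 lower (camera adjusted p = 0.0174, and adjusted p = 0.0908 with an estimated correlation). The placental cathepsins Cts3 and Ctsm rose by 5.56 and 5.52 on the log2 scale, with Cts3 saturated on 1 placenta array, and Mmp2 fell by 0.98. Cts7 fell by 0.68 as a ratio, with −0.96 to −0.09 over 17 alternatives and no call in Cy3 alone. Mmp14 and the inhibitors Timp2 and Timp3 fell as well, while the inhibitors Serpinb9e and Serpinb9g rose. Without probes whose reference signal differed between placenta and embryo arrays, an alternative chosen after seeing the data, the call of this list ended (adjusted p = 0.208, and 2.88e-08 to 0.208 over 19 alternatives).

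Of 21 lysosomal genes, 19 were higher in placenta and 1 was lower (median log2 difference 1.29, camera adjusted p = 1.31e-07, and adjusted p = 0.107 with an estimated correlation). The cathepsin Ctsl rose by 2.62 and the hexosaminidase subunit Hexb, with a value on 1 placenta array only, by 2.39, and Ctss, an immune cell cathepsin, fell by 0.83, with −0.93 to −0.42 over 17 alternatives and no call in Cy3 alone. Of 11 genes of steroid synthesis, 9 rose and none fell (median 1.31, camera adjusted p = 0.000183, and adjusted p = 0.065 with an estimated correlation), with log2 differences of 3.48 for Hsd17b2 and 2.57 for Hsd11b1. The other 2, Hsd3b1 (−0.08) and Hsd17b1 (−0.00026), did not pass the threshold. The list glycolysis and hypoxia response had 12 of 20 genes higher and 4 lower (camera adjusted p = 0.0117, and adjusted p = 0.284 with an estimated correlation). Its largest rises were Ero1a (2.85) and the glucose transporter Slc2a1 (2.60), and the lower genes were Egln1 (−0.63), Eno1 (−0.45), Pfkl and Pgk1. This call ended in 2 of 19 alternatives, with the estimated correlation and without background subtraction, with adjusted p from 7.2e-05 to 0.284, and that of Eno1 in 6 of 17.

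Of 32 nervous system genes, 26 were lower in placenta (median log2 difference −0.93, camera adjusted p = 4.31e-11, and adjusted p = 0.0575 with an estimated correlation), with Sox2 and Nefm first. Neurog1 was higher by 0.20 as a ratio and lower in Cy3 alone (−0.41), and it lost its call or reversed in 6 of 17 alternatives. Of 25 muscle genes, 18 fell (median −1.23, camera adjusted p = 5.98e-08, and adjusted p = 0.0466 with an estimated correlation). Acta1 led this list, the fast myosin light chain gene Mylpf fell by 3.02, and desmin (Des) rose by 0.38, with 0.13 to 0.86 over 17 alternatives and no call after median centring. In the cartilage and limb skeleton list, 17 of 24 genes fell and Comp, Msx2 and Chad rose (camera adjusted p = 8.73e-05, and adjusted p = 0.0575 with an estimated correlation). Twist1 led the falls, and the homeobox gene Msx1 fell by 2.33, while Comp rose by 0.71. Msx2 was higher by 0.23 as a ratio and differed by −0.07 in Cy3 alone, and it lost its call or reversed in 8 of 17 alternatives. Of 26 Hox genes, 15 fell and none rose (camera adjusted p = 0.000138, and adjusted p = 0.065 with an estimated correlation), with differences of −2.57 for Hoxa7 and −1.89 for Hoxc6.

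Of 20 genes of cell division, 18 fell and Ccne1 rose (median −0.65, camera adjusted p = 4.75e-06, and adjusted p = 0.0579 with an estimated correlation). The replication gene Mcm6 fell by 1.17 and the mitotic checkpoint gene Bub1, with a value on 1 placenta array only, by 1.14. Ccne1 rose by 0.23 and lost its call in 5 of 17 alternatives. Of 68 cytosolic ribosomal protein genes, 30 fell and 5 rose (median −0.19, camera adjusted p = 0.00515, and adjusted p = 0.284 with an estimated correlation). Rpl22 fell by 2.60 and Rpl27a by 1.23. The rises were Rps27l (0.60), Rpl19 (0.30), Rps16, Rps19 and Rps29, and Rpl19 lost its call in 3 of 16 alternatives. The Cy5 signal at Rpl19 was 58250 on embryo and 65070 on placenta arrays, the latter near the level of saturated spots.

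Markers of blood, vessels and maternal cells were listed because a placenta can hold them. Of 11 endothelial genes, 10 rose, led by Plvap (0.77) and the cadherin Cdh5 (0.76) (camera adjusted p = 0.00223, and adjusted p = 0.169 with an estimated correlation). This call ended in 2 of 19 alternatives, with the estimated correlation and in Cy3 alone, with adjusted p from 0.000176 to 0.169, and that of Plvap in Cy3 alone. Of 9 erythroid genes, 7 fell, led by Rhd (−1.82) and the erythroid transcription factor Klf1 (−1.52) (camera adjusted p = 0.00639, and adjusted p = 0.0793 with an estimated correlation). Of 10 uterine natural killer cell genes, 6 rose (camera adjusted p = 0.000914, and adjusted p = 0.149 with an estimated correlation). The granzyme gene Gzmd rose by 5.48, and Gzmc, not well above background on embryo arrays, was at least 42.3-fold higher in placenta. The natural killer markers Gzma, Ncr1, Nkg7 and Klrd1 had log2 differences of −0.01, 0.08, 0.08 and 0.15 and did not pass the threshold. The list's call ended with the estimated correlation and without probes whose reference signal differed, with adjusted p from 2.98e-06 to 0.149 over 19 alternatives.

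Another 4 lists were not called by camera. Leukocyte genes were split, 3 higher and 7 lower (adjusted p = 0.0718). This list was called in 3 of 19 alternatives, with fry, Agilent log ratios and series matrix values, with adjusted p from 0.000161 to 0.149. S100a8 was higher by 2.55, Lcp1 by 1.27 and Cd14 by 0.21, S100a9 was lower (−1.89), and C1qa was lower as a ratio (−1.08), with −1.25 to −0.15 over 17 alternatives and no call in Cy3 alone. Maternal decidua genes had 7 higher, led by Prl8a2 and osteopontin Spp1 (2.38), and 4 lower, namely Hoxa10 (−0.67), Lum (−0.64), Mmp11 and Hand2 (adjusted p = 0.147). The Cy5 signal at Spp1 was 65120 on embryo and 65130 on placenta arrays, at the level of saturated spots. Secreted proteins of fetal liver and yolk sac had 9 higher, with Amn at 2.33 and Kng1 at 1.89, and 4 lower, namely Vtn (−0.80), Itih2 (−0.74), Ambp and Itih3 (adjusted p = 0.351), and Itih2 was not called in Cy3 alone (−1.02 to −0.25 over 17 alternatives). Amn and Kng1 lacked a value on a pool array and were not in the test of this list. Imprinted genes had 15 higher, with Slc22a18 at 3.70 and Phlda2 at 2.39, and 12 lower, with Peg12 at −2.10 and Nnat at −1.84 (adjusted p = 0.881). The Cy5 signal also differed at Phlda2 and Nnat, and in Cy3 alone their differences were 4.68 and −4.14. The mean log2 difference of all 34 imprinted genes was 0.16 and the median −0.01. In all, 16 of the 20 lists were called with the preset correlation, 1 with the estimated one, the muscle list, and 20 by fry. Fry sets a list against no change and not against the other genes, and 45.4% of all tested probes were called. Its 20 calls therefore do not show that a list stands out from other genes. Adjusted over the list alone, the counts of higher and lower genes were those given above, except that 28 nervous system, 18 cartilage and 31 ribosomal genes fell and 14 labyrinth and 10 fetal liver genes rose.

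**Figure D1:**
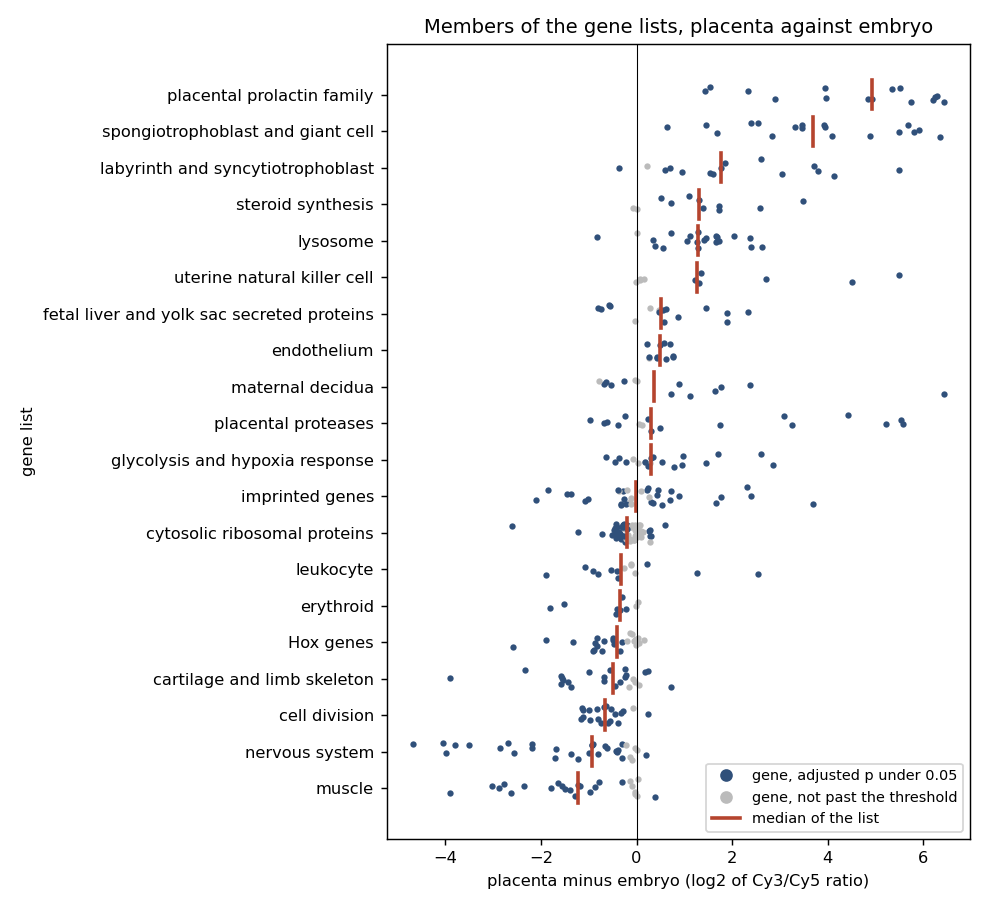
Log2 difference of each measured gene, placenta minus embryo, in the 20 gene lists, with blue points for genes past the threshold, grey points for the others and a red bar for the median of a list. The lists run from muscle (median −1.23) to the placental prolactin family (median 4.92).

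The pools were then compared with one another and with the unmixed RNAs. The named genes Prl8a2 and Procr were lower, and Sox2 and Acta1 higher, in the pool with 75% TR076 than in the pool with 25% TR076. Prl8a2 had a mean log2 ratio to the reference of 0.24 in embryo, 5.39, 5.94 and 6.47 in the pools with 75%, 50% and 25% TR076, and 6.66 in placenta. Procr went from −1.92 in embryo through 2.09, 2.99 and 3.53 in these pools to 3.90 in placenta. Sox2 fell from 4.63 in embryo through 4.17, 3.77 and 2.90 to −0.04 in placenta, and Acta1 from 3.09 through 2.79, 2.31 and 1.49 to −0.81. Of the 20 genes with the largest differences, Prl7a2, Tpbpb, Ceacam11 and Prl7d1 did not follow this order, with ratios of 7.22, 6.53, 6.49 and 5.87 in the 25% TR076 pool against 6.56, 6.30, 5.82 and 5.82 in placenta, nor did Prl8a9, with 7.21 in the 50% pool against 6.38. Of these 5 genes, all but Prl7d1 were saturated on at least 1 placenta array. At all 5 the Cy5 signal was higher on placenta than on embryo arrays, by 3.47 (Prl8a9) to 4.16 (Ceacam11) on the log2 scale. Cy3 values after loess and Aquantile normalization in the 25% TR076 pool and placenta were 14.96 and 15.5 for Prl7d1 and 15.7 and 16.14 for Tpbpb. They were 16.31 and 16.35 for Prl7a2, and 16.4 and 16.31 for Ceacam11, which stayed out of order. Among the other named genes, the group means of Prl3b1, Prl7c1, Cts3, Cts7, Phlda2, Eno1, Slc2a3, Lum, Des and Neurog1 were out of order too. With limma, 5715 of 20539 probes differed between the 75% and 25% TR076 pools, 3051 higher and 2664 lower in the 75% TR076 pool. This comparison shares no array with that of placenta and embryo. Of the 5441 probes called in both, 5440 were higher in embryo and in the 75% TR076 pool or lower in both, where independent lists would share 1299. Pools mixed from the unmixed RNAs are not independent of them, so an overlap above that number was built into the design. The other probe, which has no gene symbol and was chosen after its values were seen, was lower in placenta by 0.58 (adjusted p = 0.0441) and lower in the 75% TR076 pool by 0.73 (adjusted p = 0.025). For the 75% TR076 pool vs 25% TR076 pool, the count was 3353 in Cy3 alone and 3479 after median centring.

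**Figure D2:**
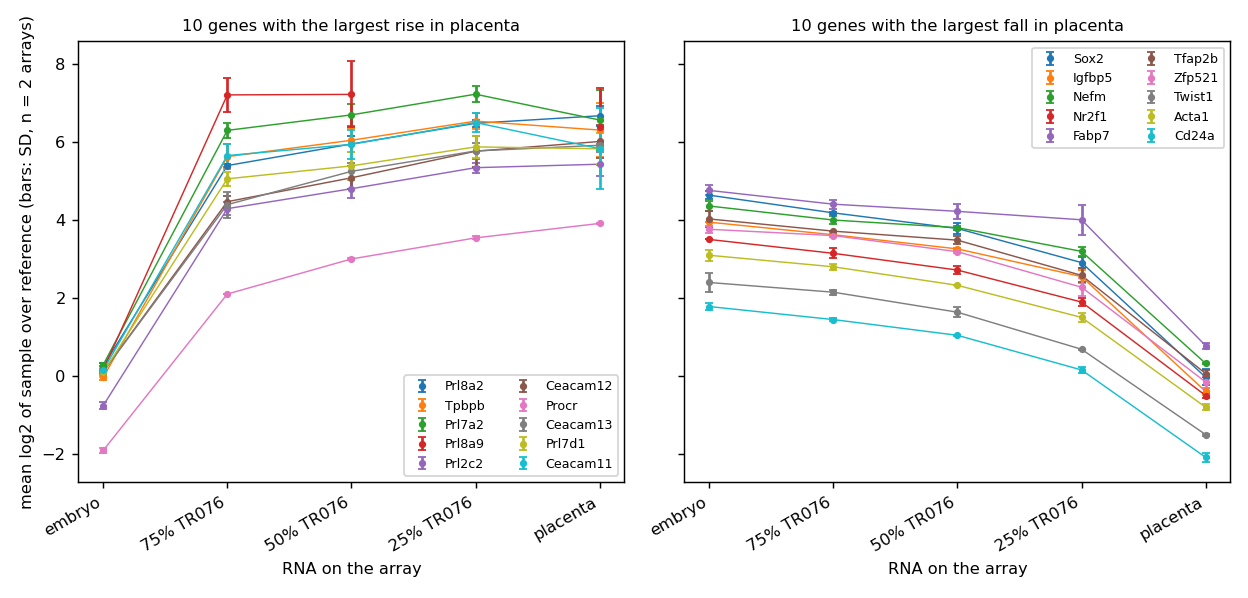
Mean log2 ratio of sample over reference, with SD of 2 arrays, for the 10 genes with the largest rise (left) and the largest fall (right) in placenta, for embryo, the pools with 75%, 50% and 25% TR076, and placenta. Pools are placed by TR076 percentage, which assigns no tissue to TR076, Prl8a9 has no point for the 25% TR076 pool because of an outlier-flagged spot, and Sox2 falls from 4.63 in embryo to −0.04 in placenta.

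The 50% pool was set against each unmixed RNA. Against embryo, 4410 probes differed, 2358 higher and 2052 lower in the pool, and over 2-fold there were 454 higher and none lower. Trophoblast genes were among the higher ones, for example Prl2c2 at 4.79 in the pool and −0.77 in embryo, and Rhox6 at 4.63 and 0.12. Against placenta, 6437 probes differed, 3236 higher and 3201 lower in the pool, with 519 and 50 over 2-fold. In a linear mix these uneven splits over 2-fold are built in. Embryo RNA diluted to a share of 50% or more cannot lower a transcript over 2-fold, whereas rises have no such bound. Falls against placenta are bounded near 2-fold in the same way. Among the named genes, Cd24a was at 1.03 in the pool and −2.10 in placenta, and Twist1 at 1.63 and −1.52. For the 50% pool vs embryo the count was 2260 after median centring, with 1626 higher and 634 lower, and 1764 in Cy3 alone, with 1143 higher and 621 lower, and it was 2907 without replicate 1 of the 50% pool. For the 50% pool vs placenta it was 3609 after median centring.

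Observed ratios between pools were set against those expected from linear mixing under both readings of TR076. For the 75% against the 25% TR076 pool, the slope of observed on expected log2 ratios over 9313 called probes was 0.961 (SD 0.0255 of the 4 array pairings, range 0.934 to 0.987) when TR076 is read as embryo, and −0.961 when it is read as placenta. The correlation across probes was 0.960 and −0.960. For the 75% against the 50% TR076 pool, the slope was 0.875 (SD 0.0337, range 0.838 to 0.912) or, with TR076 read as placenta, −0.877 (SD 0.0265). For the 50% against the 25% TR076 pool it was 1.05 (SD 0.0487, range 0.996 to 1.11) or −0.984 (SD 0.0604). With TR076 read as embryo, observed and expected log2 ratios of the 75% and 25% TR076 pools differed by a median of 0.0667.

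**Figure D3:**
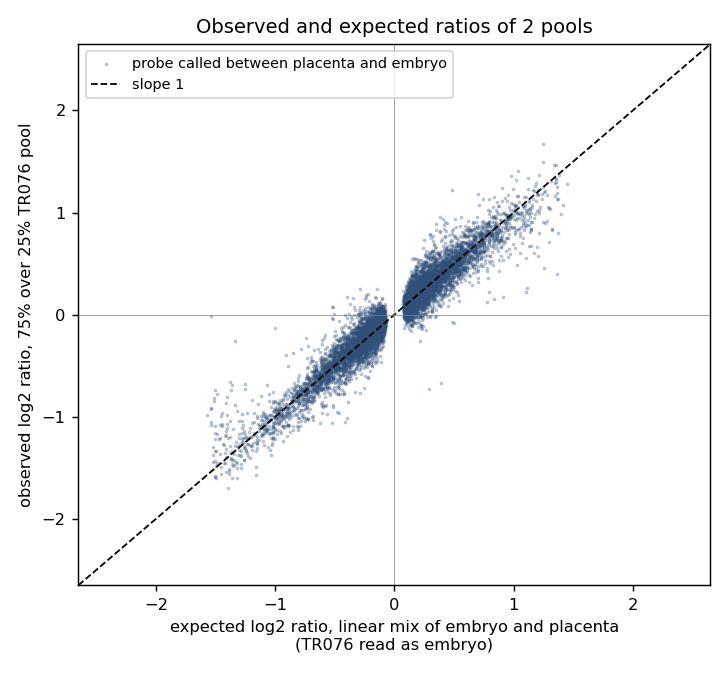
Observed log2 ratio of the 75% over the 25% TR076 pool against the ratio expected from a linear mix of embryo and placenta, with TR076 read as embryo, for each of 9313 probes called between placenta and embryo, and a dashed line of slope 1. Points lie along the line with a fitted slope of 0.961, and with TR076 read as placenta the horizontal axis changes sign.

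The embryo share of the signal was estimated for each pool from 2187 probes called over 2-fold. It was 78.2% ± 0.104 (SD, n = 2 arrays) in the 75% TR076 pool, 55.8% ± 0.131 in the 50% pool and 29.3% ± 0.853 in the 25% TR076 pool. In the 50% pool, where the nominal share needs no reading of the labels, the estimate exceeded 50% by more than the spread of the arrays. Probes higher in embryo gave 79.8%, 57.8% and 29.4% in the same order, and probes higher in placenta gave 77.4%, 54.2% and 29.1%. Least squares in place of the median for the embryo share of the 75% TR076 pool, the embryo share of the 50% pool and the embryo share of the 25% TR076 pool gave 50.8%, 29.2% and 3.43%, and without probes whose reference signal differed it gave 77.8%, 56.1% and 27.0%. At 98.7% of 2186 probes the pool means stood in the order 75%, 50%, 25% TR076 from embryo to placenta, at 0% in the opposite order, where chance gives 16.7% for each order. This argues against reading TR076 as placenta RNA, under which the 75% TR076 pool would lie nearest placenta. The labels do not give the reading, so both stay printed. Embryo arrays correlated across probes with the 75%, 50% and 25% TR076 pools at mean r of 0.898, 0.814 and 0.683, and placenta arrays at 0.740, 0.850 and 0.936.

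**Figure D4:**
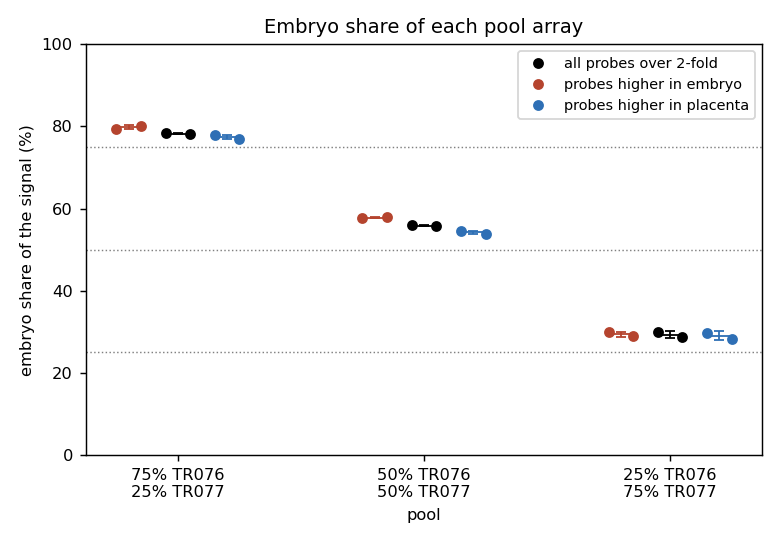
Embryo share of the signal in percent for each pool array, estimated from all probes over 2-fold (black), probes higher in embryo (red) and probes higher in placenta (blue), with the mean and SD of 2 arrays per pool. Dotted lines mark 75%, 50% and 25%, and the black means are 78.2%, 55.8% and 29.3%.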

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

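The tests in this part were chosen after the Cy5 signals of some placental genes had been seen. The reference RNA was the same on all arrays, yet in its Cy5 channel alone 748 of 20538 probes differed between placenta and embryo arrays with limma, 409 higher and 339 lower on placenta arrays, with 96 and 21 over 2-fold. For this comparison, Cy5 signals were corrected by normexp and quantile-normalized between arrays. This was singled out because the comparisons of the report use Cy5 as the divisor of each ratio and not as a measurement of its own. Of the 96 probes over 2-fold higher, 75 were also called higher in placenta in the ratio. Named genes called over 2-fold higher in Cy5 were Prl3b1, Ceacam11, Prl7a2, Cts3, Prl7d1, Tpbpb, Prl8a9, Phlda2, Prl2c2, Prl8a8, Gzmd, Ceacam12, Prl8a2, Gzmc, Prl6a1, Prl2a1 and Ceacam13, and on the embryo side Cy5 was lower on placenta arrays at Fabp7 (log2 difference −1.51) and Nnat (−2.23).

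Brighter Cy5 on the placenta arrays as a whole was not tested, because quantile normalization removes such a difference beforehand. Median raw Cy5 signals were 815 and 749 on embryo arrays and 846 and 779 on placenta arrays. After normalization, the median Cy5 difference at the 342 probes over 4-fold higher in placenta still lay 0.315 above that of all probes on the log2 scale. A constant share of Cy3 light read in the Cy5 channel would give one percentage at every probe. Among 23 unsaturated probes with Cy5 under 300 on embryo arrays and a Cy3 rise over 5000, the Cy5 rise was 0.842% to 17.8% of the Cy3 rise, and its 75th percentile was 2.66 times its 25th, so such light is not the whole source. A fixed share per probe that follows its Cy3 signal stays open. Across these 23 probes the percentages from placenta and from 50% pool arrays correlated at r = 0.947, and at 0.876 and 0.962 where no array was shared, against at most 0.587 with the probes shuffled 1000 times. Over all 252 unsaturated probes with a Cy3 rise over 1000 the r was 0.718, and −0.196 and 0.584 where no array was shared. Probes are not independent replicates, and no biological explanation was tested, because the design gives none for a common reference.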

How the results depend on the processing

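The settings that leave out probes with a differing reference signal or saturated probes, and the least squares share without the former, were chosen after seeing the data, and all others before. The count for placenta vs embryo stayed within 1.5 times 9315 under all settings run, from 6840 after median centring to 9657 in Cy3 alone. After median centring in place of loess, the count for the 75% TR076 pool vs 25% TR076 pool was 3479, for the 50% pool vs embryo 2260 (1626 higher, 634 lower, or 72.0% higher against 53.5%) and for the 50% pool vs placenta 3609. With the Cy3 channel alone the 75% against 25% count was 3353 and the 50% pool against embryo 1764 (64.8% higher). Cy3 alone also moved the median placenta minus embryo difference of all probes to −0.10, and the other scalings moved it by less. The counts with 1 array left out ranged from 8207 to 8664 for placenta against embryo, 3999 to 5005 for 75% against 25% TR076, 2907 to 4050 for the 50% pool against embryo (2907 without replicate 1 of that pool) and 4595 to 5825 for the 50% pool against placenta, with the lone array assumed to vary like the other groups.

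Slopes of the 75% against 25%, 75% against 50% and 50% against 25% TR076 pools, TR076 read as embryo, moved by more than their spread. The mixture slope 75% vs 25% TR076 pools was 0.927 with Agilent log ratios, 0.910 with median centring, 0.990 with scale normalization, 0.993 in Cy3 alone and 0.935 with probes chosen on replicate 1 and expected ratios from replicate 2. The mixture slope 75% vs 50% TR076 pools was 0.838 with a normexp offset of 0, 0.917 without background subtraction, 0.827 with Agilent log ratios, 0.925 with scale normalization, 0.773 in Cy3 alone and 0.939 as a median of observed over expected. The mixture slope 50% vs 25% TR076 pools was 0.970 with median centring, 1.22 in Cy3 alone and 0.984 as a median. Leaving out 1 array gave 0.939 to 0.983, 0.847 to 0.902 and 1.01 to 1.09. With TR076 read as placenta, slopes stayed negative throughout.

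The embryo share of the 75% TR076 pool, the embryo share of the 50% pool and the embryo share of the 25% TR076 pool often moved by more than their small spread. The 75% and 50% pools had 77.4% and 55.5% with a normexp offset of 0, 78.3% and 55.0% without background subtraction, 77.1% and 55.4% with Agilent log ratios and 77.3% and 55.4% with series matrix values. All 3 had 77.6%, 53.8% and 26.5% with scale normalization and 80.2%, 60.1% and 31.1% in Cy3 alone, and the 75% and 25% pools 77.6% and 31.1% with median centring. Least squares gave 50.8%, 29.2% and 3.43%, and without probes whose reference signal differed 77.8%, 56.1% and 27.0%, so that those probes account for most of the change. The median without them was 78.5% and 56.1% for the 75% and 50% pools. Leaving out 1 array gave 76.7% to 78.6%, 54.1% to 56.8% and 27.4% to 30.5%.

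For the gene lists, with estimated correlation 1 list was called instead of 16, and with fry 20. Leaving out 1 array kept the number at 16. Single lists kept the direction of their mean log2 difference and their side of the threshold in 355 values, lost a call in 19 and gained one in 6. Camera put the imprinted genes, never called by it, on the lower side in 6 of 20 settings. Named genes kept both in 1316 values, lost a call in 36 and reversed in 2, both in Cy3 alone, Msx2 (−0.068) and Neurog1 (−0.41). The cause of these changes was not tested, except where stated. Slide and scan date were not run as a block, because each array had its own slide. Median signals of 1.54 to 2.05 times background limit what can be said of dim probes. No paired analysis was run, because the labels pair no arrays.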

Other observations

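Of the tests in this part, that of a shift in centring was chosen before its result was seen, and the others after. Further genes of the lists, chosen after their values were seen, were these. Among placental genes, the log2 difference was 5.50 for Plac8, 5.21 for the cathepsin Ctsr, 4.89 for Psg16, 4.43 for Serpinb9g, 3.72 for Tfap2c and 3.46 for the VEGF receptor Flt1, all higher in placenta. Rhox9, saturated on both placenta arrays, was at least 153-fold higher in Cy3 there. Of the steroid synthesis list, Cyp17a1 was higher by 1.72 and the transport protein gene Star by 1.74, and Cyp11a1, not well above background on embryo arrays, was at least 2.22-fold higher in Cy3. On the embryo side were Zic1 (−3.80), Stmn2 (−3.50), the cardiac and slow troponin gene Tnnc1 (−2.88), atrial myosin heavy chain Myh6 (−2.62) and Otx2 (−1.36). Igf2, an imprinted growth factor expressed in embryo and placenta, differed by −0.13, with a value on 1 placenta array only, and did not pass the threshold (adjusted p = 0.334).

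The embryo share of the 50% pool was above 50%, and 1 factor of embryo over placenta signal per unit of pooled total RNA is a candidate explanation. Its test depends on the reading of TR076, which the labels do not give. The factor from that pool, 1.26, predicts shares of 79.1% and 29.6% for pools of 75% and 25% embryo RNA, within 0.955 percentage points of those observed if TR076 is embryo RNA, and up to 49.9 percentage points from them if it is placenta RNA. Background left in or over-subtracted is argued against by the lowest share over the background corrections, 55.0%, and a shift in the centring of the pool arrays by the share at which probes higher in embryo and probes higher in placenta meet, 55.9%. Whether the factor comes from the quantitation of the RNAs, their mRNA content or their amplification stays open. Read from the other pools, the factor was 1.19 and 1.24 with TR076 as embryo, and 10.7 and 0.138 with TR076 as placenta. The values under the placenta reading lie far from 1.26, on both sides of it. With the slopes, which are negative under that reading, they argue against TR076 as placenta RNA. Under the embryo reading, 1 factor stays a candidate. The share of the 75% TR076 pool, 78.2% ± 0.104 (SD, n = 2 arrays), lay below the predicted 79.1% by more than that SD. With the shares from this factor in place of the nominal ones, the slope was 0.902 (SD 0.0368) for the 75% against 50% TR076 pools. It was 0.959 for 75% against 25% and 1.02 for 50% against 25%.

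Of 5 measured granzyme genes from Gzmb to Gzmg, 5 rose in placenta, with a median log2 difference of 2.70. A higher share of leukocytes of all kinds is argued against by the leukocyte list, in which 7 of 14 genes were called lower in placenta under each of 8 scalings, with S100a9, C1qc, Cd52, Lyz2 and Tyrobp among them each time, while 2 or 3 were called higher. Natural killer cells in the placental tissue, a hypothesis, would bring other markers too. The median of the 5 others was 0.0828, but their Cy3 signals on placenta arrays were a median of 1.21 times those of negative controls, so this explanation and expression by placental cells cannot be told apart, and Il2rb, the brightest of them at 3.75 times the negative controls, rose by 1.23. A difference between placenta and embryo tissue itself stays open, as untested.

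No probe deviated in the 50% pool from a linear mix at the estimated share with limma variances at an adjusted p under 0.05 (lowest adjusted p = 0.132), and 734 of 20536 had an unadjusted p under 0.05, where chance gives 1027. The share was estimated from the same arrays. No probe was called against a 50% mix either, so this test did not tell the estimated share from 50%. Deviations over 0.5 on the log2 scale above the mix were measured at 35 probes, 32 of them over 4-fold higher in placenta. Among the latter kind of probe, the median deviation was 0.32 at the 106 whose reference signal differed between placenta and embryo arrays and 0.02 at the other 236.

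Between neighbouring pools, 1100 probes differed for 75% against 50% TR076 and 2485 for 50% against 25% TR076.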
